A study of Mus musculus with 10 samples.

How the data were processed

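RNA from 10 mouse cell lines or clones was sequenced, each as 2 technical duplicates per the series' design text. Per the labels' protocols, total RNA was purified with a column kit and made into standard Illumina libraries. TSC and iTSC were grown in TX medium, ESC in 2i medium and MEF in serum medium. Passage numbers in the labels were 15 to 20 for 3F clone 3 and 20 to 25 for the other clones. Per the submitters' processing notes, the tools were bcl2fastq 2.15.0.4, Trim Galore 0.3.7, TopHat2 2.0.11, Cufflinks 2.2.1 and Cuffnorm, with genome build GRCm38. The annotation release and the strandedness of the libraries were not given in the sources used here, so overlapping and antisense genes cannot be told apart from their partners.

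The deposited tables hold 39171 genes with an Ensembl identifier and symbol, and for each duplicate an FPKM and a scaled count. The authors' FPKM values are, per the file headers, FPKM per gene, that is fragments scaled by transcript length and depth, and Cuffnorm is named in the submitters' processing notes. The authors' scaled counts form a signal rather than whole numbers: between 95.9% and 96.6% of values per duplicate were whole multiples of a common step within 0.02, and between 0.143% and 0.227% lay below the step. Because of the latter no count-based test was run. Dividing each column's total by its step gave an estimated depth of 21.7 to 39.2 M fragments per duplicate and 46.3 to 72.5 M per library. Duplicates of a library correlated at 0.994 to 0.996 on the log2(FPKM + 1) scale, with a standard deviation of 0.212 to 0.251 for their differences, and 62 to 87 genes differing over 2-fold. They were averaged and counted as 1 replicate. Coordinates were taken from a GENCODE annotation of the same build for the 37691 genes whose identifier matched. Symbols shared by several identifiers (171) were assigned to the most expressed, and the others carry the identifier.

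Genes with an FPKM of at least 1 in at least 1 library were tested, 15709 in all. Values were log2(FPKM + 1), so that differences of low genes are understated. Linear models were fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend in the empirical Bayes step and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. Comparisons between cell types used all 10 libraries in a single fit, with the 6 clones as replicates of the iTSC type. Comparisons between factor sets used the same libraries with 6 groups. The comparison of strains used the 8 iTSC and TSC libraries with cell type as a covariate. The spread of ESC and MEF, with 1 library each, was assumed equal to that of the other groups. Differences are given with the standard error from the moderated variance, and levels as the mean FPKM with its SD.

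For each of 16 gene lists, camera was run with a preset correlation of 0.01 between genes and again with an estimated correlation, on iTSC against TSC, MEF and ESC, and adjusted over the lists within a comparison. The test fry was run on the same lists, for changes one way and for changes in either direction. It does not compare a list with other genes. The lists covered trophoblast stem cell, trophoblast differentiation, pluripotency, fibroblast and mesenchyme, epithelial, extraembryonic endoderm, mesoderm and neural, imprinted, DNA methylation, germline, cell cycle, p53 and senescence, interferon-stimulated, FGF and TGF-beta response, glycolysis and hypoxia, and cholesterol synthesis genes. Counts adjusted over the list alone use the p-values of the list's members only. The genes named in the text are the 8 called genes with the largest rise and the 8 with the largest fall in each comparison, without predicted, unnamed, ribosomal, histone, small RNA and mitochondrial genes, plus members of the lists, the 3 reprogramming factors and 5 sex chromosome genes. Other genes, and the members of lists given as examples, were chosen after their values were seen. Library similarity was Pearson's r across the tested genes, with average linkage on 1 - r.

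The samples, lists, designs, named-gene rule and most alternatives were fixed before the data were examined. Those alternatives were pseudocounts of 0.1 and 5, filters of 2 or more libraries or none, quantile normalization, rescaling to a common total, robust empirical Bayes, a strain covariate, a fit of 8 libraries, the mean of the factor sets, and leaving out each clone and TSC line in turn. Alternatives added after seeing the data were the scaled counts, each duplicate alone, leaving out the 3 clones of highest mitochondrial share, and leaving out fibroblast genes. The model was tested on simulated data with the real means and residual spread of 15709 genes, of which 200 were changed. The simulated genes varied independently of each other, so recovery in the real data can be lower. Only genes above a minimum mean level were changed, so recovery of lower genes was not measured. The 200 changed genes were also far fewer than the 4697 and 2534 called in the real data against MEF and ESC. Recovery in those contrasts can therefore differ. For iTSC against TSC it recovered 46.3% of changes of 1.5 on the log2 scale, 82.1% of changes of 2.5 and 100% of changes of 4, with 5 false calls. For iTSC against MEF these were 23.9%, 68.7% and 92.4% with 3 false calls, for iTSC against ESC 28.4%, 62.7% and 86.4% with 6, and for 3F against 12F 19.4%, 71.6% and 89.4% with 4. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used to read the tables, and matplotlib 3.10.9 for figures.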

Results

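The study measured gene expression by RNA sequencing in 10 mouse cell lines or clones. It converted fibroblasts into induced trophoblast stem cells (iTSC), cells meant to resemble the stem cells of the placental lineage, by forced expression of transcription factors. The labels name 6 iTSC clones by factor set, with 2 clones each of the 3F, 4F and 12F sets. The references were 2 lines of embryo-derived trophoblast stem cells (TSC), 1 embryonic stem cell line (ESC) and 1 culture of mouse embryonic fibroblasts (MEF). Each library was sequenced as 2 technical duplicates, and their mean was counted as 1 replicate. Estimated fragments per library, summed over the duplicates, ran from 46.3 M in iTSC 12F clone 5 to 72.5 M in MEF. Between 12244 and 12685 genes per library reached an FPKM (fragments scaled by transcript length and sequencing depth) of 1. ESC and MEF had 1 library each, so their values carry no error of their own, and nothing in the labels says whether clones came from separate conversions. The p-values therefore measure the spread between these clones and lines only.

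The mitochondrial share of fragments differed between libraries. It was 10.9% and 9.48% in the 12F clones 5 and 4, 9.90% in 4F clone 3, 6.75% in 3F clone 4, 4.68% in 3F clone 3 and 3.92% in 4F clone 1. The TSC lines had 4.76% and 3.74%, ESC had 2.37% and MEF had 1.95%.

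The first question was which cell type the converted clones resembled. Across 15709 expressed genes, Pearson's r between an iTSC clone and a TSC line ran from 0.905 to 0.970 over 12 pairs, with a median of 0.943. The 2 TSC lines correlated with each other at 0.954, within that range, and the iTSC clones among themselves at 0.917 to 0.977. The clones correlated less with ESC, at 0.817 to 0.854, and least with MEF, at 0.702 to 0.752. These are correlations across genes, which are not independent replicates. Average-linkage clustering placed both TSC lines with both 3F clones and 4F clone 1, and joined 12F clones 4 and 5 and 4F clone 3 into a separate branch. The latter 3 clones were those with the highest mitochondrial shares.

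**Figure D1:**
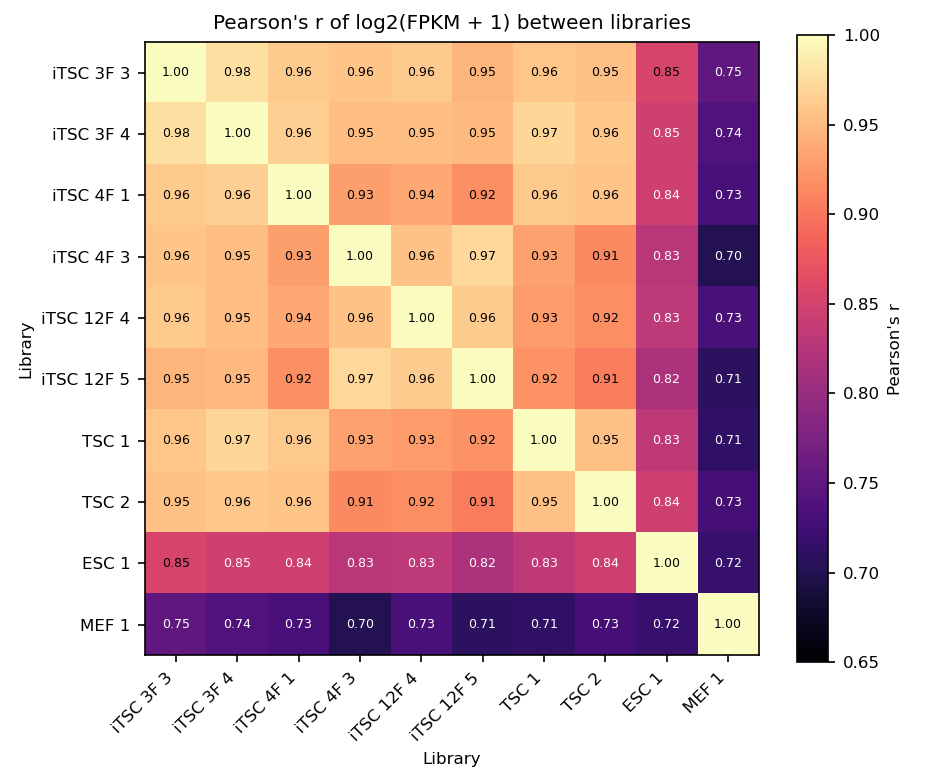
Pearson's r of log2(FPKM + 1) between each pair of the 10 libraries, across 15709 expressed genes, with library names on both axes and r as color and number. The clones and TSC lines form a block of 0.905 or more, while every value against MEF is at most 0.752.

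The 3 factors known from the study to make up the 3F set were abundant in every clone. Gata3 (ENSMUSG00000015619, chromosome 2, 9857078 to 9890034, GRCm38), a zinc finger factor of early trophectoderm, stood at 56.3 ± 26.4 FPKM in iTSC (SD, n = 6) and 88.0 ± 11.4 in TSC (SD, n = 2), against 1.94 in ESC and 4.72 in MEF. Eomes (ENSMUSG00000032446, chromosome 9, 118478212 to 118486132), a T-box factor needed for trophoblast stem cells, stood at 82.1 ± 22.4 in iTSC and 41.5 ± 6.89 in TSC, with 14.1 in ESC and 0.289 in MEF. Tfap2c (ENSMUSG00000028640, chromosome 2, 172549593 to 172558622), an AP-2 family factor of the trophoblast, stood at 131 ± 21 in iTSC and 64.9 ± 17.2 in TSC, with 5.42 in ESC and 0.148 in MEF. Gata3 ranged from 34.2 in 12F clone 5 to 103 in 4F clone 1. Gene-level values do not separate transcripts of an introduced copy from those of the cell's own gene.

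The comparison of iTSC with MEF asked what differed between the converted clones and the fibroblast culture. MEF were grown in serum medium and iTSC in TX medium, so cell type and medium cannot be told apart here. Most trophoblast stem cell genes of the fixed list were high in the clones and collagen and actin genes of fibroblasts were low. The X-linked homeobox gene Rhox5 stood at 2622 ± 676 FPKM in iTSC (SD, n = 6) against 0.812 in MEF (log2 difference 10.47 ± 0.43 SE, limma adjusted p = 2e-07). Its cluster neighbours Rhox6 (319 ± 259) and Rhox9 (350 ± 286) were listed at 0 in MEF. Hand1, a basic helix-loop-helix factor of trophoblast giant cells, stood at 322 ± 161 against 0.133, and Krt8, a keratin of simple epithelia, at 745 ± 688 against 1.07. The other genes with the largest rises were Bex1 (856 ± 347 against 1.22), Utf1, a chromatin factor of pluripotent cells (290 ± 130 against 0.0253), and Phlda2, an imprinted regulator of placental growth (381 ± 413 against 0.0744). The largest falls were in Acta2, smooth muscle actin, from 4468 FPKM in MEF to 1.81 ± 1.53 in iTSC (log2 difference -10.83 ± 0.81 SE, adjusted p = 1.4e-05), and in the fibrillar collagens Col1a1 (3602 against 1.53 ± 1.49), Col1a2 (2906 against 1.11 ± 1.49) and Col3a1 (860 against 0.0966 ± 0.0796). Lox, which cross-links collagen, Bgn, Thbs1 and Actg2 completed the 8 largest falls, with log2 differences of -9.88, -9.59, -9.29 and -9.15.

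In the lists fixed before the data were examined, 19 of 23 trophoblast stem cell genes were higher in iTSC than in MEF and none was lower, also 19 when adjusted over the list alone (camera adjusted p = 1.8e-11, and adjusted p = 0.015 with an estimated correlation). The factors Gata3, Eomes and Tfap2c of the 3F set were among these 19, and introduced copies cannot be told from the cells' own genes. The further factors of the larger sets were not identified here, so levels of other genes may also include introduced copies in those clones. Also among the 19 was Elf5, a factor that maintains trophoblast stem cells, at 183 ± 48.7 FPKM against 0.0351. Cdx2, a specifier of trophectoderm, stood at 27.0 ± 8.68 and was listed at 0 in MEF. All 35 measured fibroblast and mesenchyme genes were lower, also 35 adjusted over the list alone (camera adjusted p = 2.9e-21, and adjusted p = 0.019 with an estimated correlation). Thy1, a surface marker of fibroblasts, fell from 818 to 2.08 ± 1.66, and Twist1 and Zeb1, which repress epithelial genes, fell from 33.6 to 1.10 ± 1.11 and from 25.8 to 1.47 ± 0.643. Vim, an intermediate filament gene, fell from 5432 to 196 ± 149 (adjusted p = 0.048), and its call was lost in 9 of 20 other settings. Cell cycle genes rose, with 24 of 27 higher over all genes and 24 adjusted over the list alone (camera adjusted p = 1.7e-12, and adjusted p = 0.025 with an estimated correlation). Mki67, a marker of cycling cells, stood at 27.9 ± 7.87 against 3.51, and the mitotic genes Top2a and Ccnb1 at 229 ± 42.6 against 17.6 and 88.1 ± 23.5 against 7.38.

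Of 26 epithelial genes 22 were higher, 23 adjusted over the list alone (camera adjusted p = 4e-12, but adjusted p = 0.20 with an estimated correlation). They included the adhesion genes Cdh1 (156 ± 20.9 FPKM against 0.0502) and Epcam (148 ± 32.8 against 0.0857). Of 28 pluripotency genes 11 were higher, and 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.4e-05, adjusted p = 0.079 with an estimated correlation). Sox2 (103 ± 44.7 against 0.657) and Esrrb (98.2 ± 53.3 against 0.0541), which the trophoblast stem cell list also holds, were among these, as was Zfp42 (53.02 ± 9.73 against 0.0198). Pou5f1 (1.20 ± 0.661 against 0.683) and Nanog (1.09 ± 0.474 against 0.339) were not called, and the sign of the Pou5f1 difference of 0.33 turned to -0.95 on scaled fragment counts. Among the 16 DNA methylation genes 7 were higher, 7 adjusted over the list alone, including the methyltransferase Dnmt3b (60.5 ± 24.6 against 0.65) and the maintenance cofactor Uhrf1 (61.3 ± 5.99 against 8.35). The de novo cofactor Dnmt3l (43.5 ± 27.5 against 0.794, adjusted p = 0.045) lost its call in 9 of 20 other settings. The list's camera adjusted p was 0.024, and adjusted p = 0.24 with an estimated correlation. Imprinted genes went both ways, with 4 of 38 higher and 16 lower, or 6 and 18 adjusted over the list alone (camera adjusted p = 0.029 for lower, adjusted p = 0.099 with an estimated correlation). Igf2, not called, stood at 3133 ± 1172 against 2970, and the sign of its log2 difference of -0.02 turned in 3 other settings. Dlk1 fell from 369 to 1.15 ± 1.43 and its neighbour Meg3 from 110 to 1.37 ± 2.04. Of 22 p53 and senescence genes 8 were lower and 1 higher, or 9 and 1 adjusted over the list alone, including the cell cycle inhibitors Cdkn1a (635 against 74.1 ± 29.2), Cdkn2b (150 against 6.88 ± 2.24) and Cdkn2a (332 against 71.4 ± 28.9). Their camera adjusted p was 0.075. Of 26 germline genes 5 were higher, 3 adjusted over the list alone (camera adjusted p = 0.0019, adjusted p = 0.50 with an estimated correlation). Of 24 trophoblast differentiation genes 6 were higher and 1 lower, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0084, adjusted p = 0.50 with an estimated correlation).

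The remaining lists had camera adjusted p from 0.31 to 0.90 against MEF. Interferon-stimulated genes had 2 higher and 7 lower of 24, the same counts adjusted over the list alone, and Bst2 was among those higher (301 ± 56.4 FPKM against 34.2). Ifit1 was among those lower (0.213 ± 0.126 against 2.41), a call lost in 1 other setting. Extraembryonic endoderm had 1 higher and 3 lower of 10, or 3 and 3 adjusted over the list alone, with a median log2 difference of 0.68 and a mean of -0.14. Mesoderm and neural genes had 2 higher and 4 lower of 12 (3 and 5 adjusted over the list alone). FGF and TGF-beta response genes had 5 lower of 23, glycolysis and hypoxia genes 4 higher and 3 lower of 26, and cholesterol synthesis genes 2 higher and 3 lower of 24, each count also standing adjusted over the list alone. In all, limma called 4697 of 15709 genes between iTSC and MEF at an adjusted p under 0.05 and a log2 difference of at least 1, with 1738 higher and 2959 lower. On scaled fragment counts, an alternative chosen after seeing the data, 2638 were higher and 2974 lower. Without the 3 clones of highest mitochondrial share it called 4518, of which 4000 were called with all clones.

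**Figure D2:**
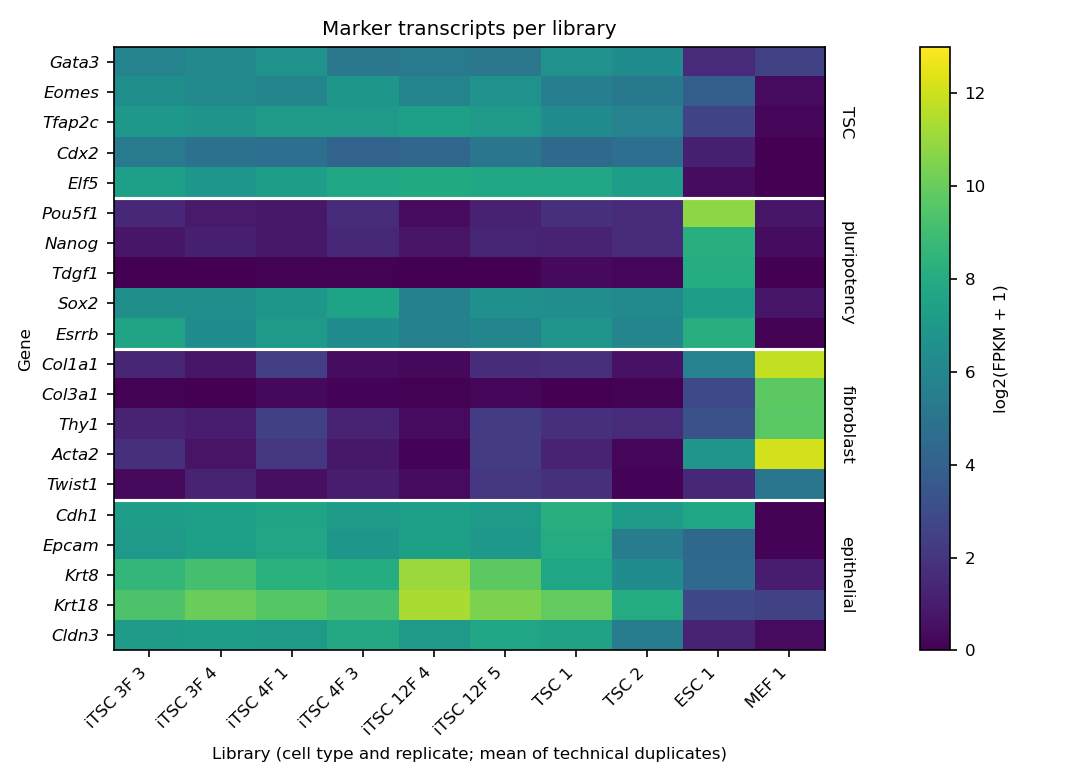
FPKM on a log2(FPKM + 1) color scale for 20 marker genes (rows) in the 10 libraries (columns), grouped as TSC, pluripotency, fibroblast and epithelial markers. Tfap2c is at 52.7 FPKM or more in every clone and TSC line, Pou5f1 is high in ESC only (1790 FPKM), and Col1a1 is highest in MEF (3602 FPKM) with 53.4 FPKM in ESC.

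The comparison of iTSC with ESC asked how the clones differed from pluripotent cells. ESC were grown in 2i medium and iTSC in TX medium, so cell type and medium cannot be told apart here. Pou5f1 and Nanog were nearly off in the clones, while Sox2, Esrrb and Utf1 were expressed and not called. Pou5f1, which encodes OCT4, fell from 1790 FPKM in ESC to 1.20 ± 0.661 in iTSC (SD, n = 6; log2 difference -9.73 ± 0.45 SE, limma adjusted p = 1.4e-06), and Nanog fell from 285 to 1.09 ± 0.474. The other largest falls were Tdh, a threonine dehydrogenase (469 against 0.261), Tdgf1, a NODAL co-receptor (265 against 0.0210), Dppa5a (2117 against 12.8), Trh (202 against 0.0980), the imprinted noncoding RNA Rian (303 against 0.780) and Calcoco2 (124 against 0.341). The largest rises were Igf2, an imprinted growth factor (3133 ± 1172 against 8.67), Hand1 (322 ± 161 against 0.232), the keratins Krt18 (1170 ± 773 against 5.87) and Krt7 (140 ± 84.9 against 0.536), Elf5 (183 ± 48.7 against 0.346), Sct (294 ± 312 against 0.884), Rhox9 (350 ± 286 against 0.999) and Rhox6 (319 ± 259 against 1.53).

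Of 28 pluripotency genes 20 were lower and none higher in iTSC than in ESC, 22 adjusted over the list alone (camera adjusted p = 7.8e-17, and adjusted p = 0.010 with an estimated correlation). Klf4 was lower at 8.50 ± 2.47 FPKM against 91.3 (adjusted p = 0.035), a call lost in 8 of 21 other settings. Zfp42 was lower at 53.02 ± 9.73 against 238 (adjusted p = 0.0039). The genes that did not pass included Sox2 (103 ± 44.7 FPKM against 152), Esrrb (98.2 ± 53.3 against 288) and Utf1 (290 ± 130 against 127). Of 23 trophoblast stem cell genes 15 were higher, and 17 higher and 2 lower adjusted over the list alone (camera adjusted p = 3.9e-10, and adjusted p = 0.010 with an estimated correlation). Cdx2 stood at 27.0 ± 8.68 against 1.19, Tfap2c at 131 ± 21 against 5.42 and Eomes at 82.1 ± 22.4 against 14.1. The 15 included Gata3, Eomes and Tfap2c of the 3F set, whose introduced copies are not separated. The same limit may hold for other genes in clones of the larger sets, whose further factors were not identified here. Epithelial genes had 14 of 26 higher, 18 adjusted over the list alone (camera adjusted p = 4.2e-08, but adjusted p = 0.38 with an estimated correlation). Cldn3, a tight junction gene, stood at 163 ± 41.1 against 1.46. Epcam stood at 148 ± 32.8 against 20.1 (adjusted p = 0.032), a call lost in 6 of 21 other settings, while Cdh1 was 156 ± 20.9 against 199 and was not called.

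Germline genes had 9 of 26 lower and 1 higher in iTSC than in ESC, the same counts adjusted over the list alone (camera adjusted p = 0.0041, adjusted p = 0.51 with an estimated correlation), with Dazl, an RNA-binding protein of germ cells, at 0.942 ± 0.836 FPKM against 33.2. DNA methylation genes had 6 of 16 lower and 1 higher, also 6 and 1 adjusted over the list alone (camera adjusted p = 0.018, adjusted p = 0.38 with an estimated correlation). The methylcytosine oxidases Tet1 (2.06 ± 2.14 against 43.9) and Tet2 (1.20 ± 0.391 against 30.0) were among those lower. Cell cycle genes had 9 of 27 lower, 9 adjusted over the list alone (camera adjusted p = 0.010, adjusted p = 0.38 with an estimated correlation). The 9 included the replication helicase genes Mcm2 to Mcm7, with Mcm5 at 66.1 ± 8.95 against 216. Pcna stood at 81.9 ± 15.0 against 188, a call lost in 2 other settings. Fibroblast and mesenchyme genes had 12 of 35 lower, 13 adjusted over the list alone (camera adjusted p = 2.3e-05, adjusted p = 0.31 with an estimated correlation). ESC itself carried these transcripts at a low level, with Acta2 at 109 FPKM and Col1a1 at 53.4. Trophoblast differentiation genes had 3 of 24 higher, 3 adjusted over the list alone (camera adjusted p = 4.3e-04, adjusted p = 0.44 with an estimated correlation). Interferon-stimulated genes had 5 higher and 2 lower of 24, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.028, adjusted p = 0.53 with an estimated correlation), and Bst2 was higher (301 ± 56.4 against 26.2).

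Imprinted genes had 7 higher and 7 lower of 38, or 8 and 10 adjusted over the list alone, with Cdkn1c, a placental cell cycle inhibitor, at 183 ± 179 FPKM in iTSC against 1.77 in ESC. The imprinted list and the others below had camera adjusted p from 0.16 to 0.99 against ESC. Extraembryonic endoderm had 2 higher and 1 lower of 10 (3 and 1 adjusted over the list alone), where Gata4 (8.76 ± 4.04 against 0.930, adjusted p = 0.042) lost its call in 9 of 21 other settings, and mesoderm and neural genes 2 lower of 12 (1 higher and 2 lower adjusted over the list alone), with a median log2 difference of 0.13 and a mean of -0.24. FGF and TGF-beta response had 1 higher and 5 lower of 23, with a median of 0.23 and a mean of -0.16, and glycolysis and hypoxia 4 higher and 2 lower of 26, with a median of -0.19 and a mean of 0.24. Their counts were the same adjusted over the list alone. Among p53 and senescence genes 1 of 22 was higher, 1 adjusted over the list alone, and among cholesterol synthesis genes 2 of 24, 1 adjusted over the list alone. In all 2534 genes were called between iTSC and ESC, with 1049 higher and 1485 lower. With FPKM rescaled to a common total the split was 561 higher and 1783 lower, on scaled fragment counts 1650 and 1516, and with a pseudocount of 5 the count was 1470.

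The embryo-derived lines served as the reference for these contrasts. They were grown in TX medium like the clones, so the same limit of medium applies. TSC differed from MEF in 4295 genes (1677 higher, 2618 lower) and from ESC in 2316 (975 higher, 1341 lower, or 553 and 1353 with FPKM rescaled to a common total, 1380 and 1328 on scaled fragment counts, and 936 and 904 with an FPKM of at least 1 required in 2 or more libraries), so which direction held the majority depended on the setting. On scaled fragment counts the split against MEF was 2415 higher and 2667 lower. With a pseudocount of 5 the count against ESC was 1381. The genes leading TSC against MEF overlapped those of the clones, with Rhox5 at 2068 ± 766 FPKM (SD, n = 2) and Acta2 at 0.766 ± 0.879, and against ESC Igf2 stood at 3722 ± 1178 and Pou5f1 at 2.30 ± 0.322. Trap1a (213 ± 33.9, listed at 0 in MEF) and Morc4 (464 ± 229 against 2.32 in ESC) were among the largest rises in TSC. Against MEF, 1277 genes were higher in both iTSC and TSC and 2362 lower in both, and none was called in opposite directions. Independent lists of those lengths would share 186 and 493. Against ESC, 695 were higher in both and 1133 lower in both, where independent lists would share 65 and 127. Both contrasts used the same control library, and in simulations of unchanged groups the log2 differences of iTSC and TSC correlated at 0.754 against MEF and 0.761 against ESC. The observed correlations were 0.944 and 0.897. The covariance was 2.53 against MEF, with 0.2 in the simulations, and 1.31 against ESC, with 0.206. Part of the excess may come from the shared control, since 1 library cannot be split.

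The central comparison asked how far the clones differed from embryo-derived TSC. Trophoblast factors differed in how close they lay, with Cdx2 at 27.0 ± 8.68 FPKM in iTSC (SD, n = 6) and 23.8 ± 3.46 in TSC (SD, n = 2), and Elf5 at 183 ± 48.7 and 182 ± 41.1. Their log2 differences were 0.12 ± 0.34 and -0.02 ± 0.30 (SE). The signs of both turned under other settings. Tfap2c and Eomes were 2.02 and 1.91 times as high in iTSC on the log2(FPKM + 1) scale, and neither passed (limma adjusted p = 0.32 and 0.38). Gata3 was at 56.3 ± 26.4 against 88.0 ± 11.4 and was not called (adjusted p = 0.45). Limma called 5 of 15709 genes, all lower in iTSC, and 1927 genes had an unadjusted p under 0.05. On scaled fragment counts it called 2 higher and 3 lower, so the single direction depended on the measure. All 5 genes of the main fit were at most 0.755 FPKM in every clone, where adding 1 before the log narrows the spread between clones. Fam166b (ENSMUSG00000042788, chromosome 4, 43427019 to 43429134) stood at 0.533 ± 0.222 against 4.56 ± 0.700 (log2 difference -1.87 ± 0.17 SE, adjusted p = 0.010), and its call was lost in 8 of 22 other settings. The other 4 were unnamed noncoding transcripts, given here after their values were seen. Gm15199 (chromosome 10, 42740539 to 42758660, antisense) was at 0.160 ± 0.143 against 8.73 ± 0.395, with a log2 difference of -3.08 ± 0.14 (adjusted p = 1.5e-04). Gm11795 (chromosome 4, 7759670 to 7763930) was at 0.265 ± 0.153 against 9.50 ± 1.64, Gm13393 (chromosome 2, 29088666 to 29094501) at 0.133 ± 0.122 against 6.18 ± 1.35, and Gm16320 (chromosome 10, 119429367 to 119455379, antisense) at 0.0837 ± 0.0593 against 1.63 ± 0.67. The last lost its call in 14 of 22 other settings, Gm11795 in 2 and Gm13393 in 1. The count of 5 rests on few lines. It was 24 without TSC line 1, 14 without TSC line 2, and 1 without the 3 clones of highest mitochondrial share. It was 3 with a pseudocount of 0.1, with the factor sets weighted equally or with technical duplicate b alone. With the pseudocount of 0.1, 2 of the 3 were among the 5.

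No member of any fixed list was called between iTSC and TSC over all genes. Adjusted over the list alone, 2 of 23 trophoblast stem cell genes were higher in iTSC, Tfap2c and the Plet1 gene 1600029D21Rik (168 ± 31.1 FPKM against 72.1 ± 30.2). The list's camera adjusted p was 0.26, and fry, which asks whether members change in either direction, gave a mixed adjusted p = 0.0049, the only list under 0.05. Of 24 interferon-stimulated genes 3 were higher over the list alone, Rsad2 (1.40 ± 0.426 against 0.180 ± 0.0882), Usp18 (2.17 ± 1.16 against 0.0863 ± 0.00409) and Rtp4 (2.59 ± 1.40 against 0.265 ± 0.0288). Isg15, not called, was at 14.9 ± 12.8 against 1.16 ± 0.326, and was highest in the 12F clones 5 (34.1) and 4 (27.8), with 9.67 in 4F clone 3. The interferon-stimulated list as a whole had a camera adjusted p = 1.9e-04 and adjusted p = 0.88 with an estimated correlation. The trophoblast differentiation list lay higher in iTSC with a camera adjusted p = 8.4e-05 (24 genes measured, median log2 difference 0.86), and adjusted p = 0.88 with an estimated correlation. For the epithelial list these were 0.0052 and adjusted p = 0.88 with an estimated correlation, with Krt19 at 222 ± 243 against 24.3 ± 3.71, Krt8 at 745 ± 688 against 143 ± 88.6 and Krt7 at 140 ± 84.9 against 37.4 ± 21.4, none of them called. Other members split the 2 TSC lines, with Cldn7 at 386 in line 1 and 4.31 in line 2, Epcam at 254 and 43.6, Cldn4 at 540 and 101 and Ap1m2 at 94.4 and 4.12, line 1 above and line 2 below every clone. Vim was at 6.81 and 269. Krt8 was highest in 12F clone 4 (2077 FPKM), as was Syna, a syncytiotrophoblast fusion gene (23.1), while Prl3d1, a giant cell hormone, was at 11.5 in 4F clone 1 and 10.6 in 12F clone 4. Without the 3 clones of highest mitochondrial share 7 lists passed with the preset correlation, against 3 with all clones. In the germline list 1 of 26 genes passed when adjusted over the list alone, Dpep3, lower at 3.13 ± 2.76 against 19.22 ± 4.45, and the list's camera adjusted p was 0.55. The lists for pluripotency, fibroblast and mesenchyme, extraembryonic endoderm, mesoderm and neural, imprinted, DNA methylation, cell cycle, p53 and senescence, FGF and TGF-beta response, glycolysis and hypoxia, and cholesterol synthesis had 0 genes called adjusted over the list alone and camera adjusted p from 0.15 to 0.98. For imprinted genes the median (-0.03) and mean (-0.10) were below 0 and the camera direction up, and for cell cycle genes the median was -0.01 and the mean 0.03. As a test of whether a list's genes moved one way, fry gave adjusted p from 0.68 to 0.99 between iTSC and TSC, and under 0.05 for 13 of 16 lists against MEF and 11 against ESC. For changes in either direction all 16 were under 0.05 against both. Among genes chosen after their values were seen, Alkbh3, a DNA and RNA demethylase, was at 17.6 ± 6.91 against 1.48 ± 0.193 (adjusted p = 0.14), Tbx4 at 1.08 ± 0.347 against 5.30 ± 0.370 (adjusted p = 0.067) and Mme at 2.46 ± 1.16 against 19.9 ± 8.32 (adjusted p = 0.18).

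The factor sets were compared to ask whether the number of factors left a difference between the clones, with 2 clones in each. Limma called 0 genes between 3F and 4F, 0 between 3F and 12F and 0 between 4F and 12F, while 415, 1343 and 997 genes had an unadjusted p under 0.05. Phlda2, Rhox6 and Rhox9 had their highest levels in the 12F clones without passing the test. Phlda2 stood at 903 ± 149 FPKM in 12F (SD, n = 2) against 84.9 ± 6.58 in 3F and 155 ± 90.2 in 4F (adjusted p = 0.35 and 0.52). Rhox6 stood at 647 ± 88.7 in 12F against 158 ± 31.2 and 153 ± 54.1, and Rhox9 at 715 ± 69.2 against 189 ± 52.2 and 146 ± 44.4. Cstf2t, an RNA 3' end processing gene chosen after its values were seen, was at 0.0614 ± 0.0619 in 12F, 7.14 ± 1.34 in 3F and 8.10 ± 3.91 in 4F, and at 0.0869 and 0.0889 in the TSC lines. Other placental genes went either way, with Sct at 498 and 841 in the 12F clones 5 and 4 against 62.5 to 147 in the other clones, but Ctsj at 26.1 and 27.0 in the 4F clones 3 and 1 against 0.56 and 11.4 in the 12F clones 5 and 4. Both 12F clones had high mitochondrial shares, but 4F clone 3, with 9.90%, had Phlda2 at 219, Rhox6 at 191, Rhox9 at 178 and Cstf2t at 5.34. The counts changed when 1 library was left out, to at most 4 between 3F and 4F (without 3F clone 4), 4 between 3F and 12F (without 12F clone 4 or without 3F clone 4) and 6 between 4F and 12F (without 12F clone 4).

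Strain varied within both cell types, with 1 of 6 clones and 1 of 2 TSC lines of C57BL/6 and the rest C57BL/6 x 129. Among these 8 libraries, with cell type as a covariate, limma called 2 genes, both outside the rule for named genes and chosen after their values were seen. Gm25057 (chromosome 15, 99174850 to 99174937, a small noncoding RNA) stood at 6.84 and 7.09 FPKM in the C57BL/6 libraries and was listed at 0 in the other 6 (adjusted p = 3.9e-05). Gm8730 (chromosome 8, 102864845 to 102865798) was at 0.192 and 1.83 FPKM in C57BL/6 and 49.5 ± 18.2 in the others (SD, n = 6; log2 difference -5.01 ± 0.40 SE, adjusted p = 0.013). Their calls were lost in 3 and 7 of 18 other settings. The log2 difference of Gm25057 was 2.99 and ran from 0.54 to 6.14 over the other settings. On scaled fragment counts and with technical duplicate b alone, 0 genes were called higher in C57BL/6. The call of Gm25057 thus rests on the measure and on the duplicate used, and the number of fragments behind it was not examined. Gm9805, also chosen after its values were seen, reached an adjusted p of 0.0022 with a log2 difference of 0.98, under the threshold, and was listed at 0 in the other 6 libraries, but its highest level, 13.2 FPKM, was in ESC, which is C57BL/6 x 129. With FPKM rescaled to a common total 2 genes were higher and 0 lower. An unadjusted p under 0.05 was reached by 390 genes. The count of 2 called genes fell to 1 without 12F clone 4 or 4F clone 3. Without 3F clone 4 the strain term came down to TSC line 2 against TSC line 1. Without either TSC line it came down to 3F clone 4 against the other clones. Such fits compare single lines, so their counts do not measure strain. The TSC lines also differed in Xist (81.7 FPKM in line 1, 0.681 in line 2) and Ddx3y (0.0924 and 31.2). Strain and such line differences cannot be told apart between them.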

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

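The rule applied here was fixed before the data were examined, but part of the genes it was applied to were chosen after their values were seen. Among the 6 iTSC clones, 3 values stood apart from the other clones by more than Dixon's 95% critical value for the gap over the range of log2(FPKM + 1), out of 92 measures tested. Chance flags about 1 in 20. Rhox5 stood at 3970 FPKM in 12F clone 5 and at 2120 to 2550 in the other clones, a gap of 0.705 of the range. Dppa5a stood at 47.5 FPKM in 4F clone 1 and at 3.03 to 8.98 in the others, a gap of 0.635 of the range. Ccnb1, a mitotic cyclin, stood at 134 FPKM in 4F clone 1 and at 68.6 to 86.8 in the others, a gap of 0.65 of the range.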

How the results depend on the processing

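The scaled fragment counts, each technical duplicate alone, and leaving out the 3 clones of highest mitochondrial share or the fibroblast genes were chosen after seeing the data. Of 166 named gene results, 117 were called, of which 103 kept the call in every setting run, 14 lost it in at least 1 and 0 changed sign. Of the 49 not called, 4 gained a call and 5 changed sign in at least 1 setting. For iTSC vs TSC, the count of 5 fell to 3 with a pseudocount of 0.1 and to 3 with the mean of the factor sets, and to 3 with technical duplicate b alone and 1 without the 3 clones with over 9% mitochondrial reads. For iTSC vs ESC a pseudocount of 5 gave 1470 and for TSC vs ESC 1381. For C57BL/6 vs C57BL/6 x 129 the count of 2 became 5 with a pseudocount of 0.1, 1 with a pseudocount of 5, 1 on scaled fragment counts and 1 with duplicate b alone. With duplicate b alone iTSC_3F vs iTSC_4F gave 2 and iTSC_3F vs iTSC_12F gave 4, and without the 3 clones iTSC_3F vs iTSC_4F gave 1. The causes were not tested.

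Leaving out 1 clone or line at a time gave 4 to 24 calls for iTSC vs TSC, 0 to 4 for iTSC_3F vs iTSC_4F, 0 to 4 for iTSC_3F vs iTSC_12F, 0 to 6 for iTSC_4F vs iTSC_12F, 1 to 20 for C57BL/6 vs C57BL/6 x 129, and 2 to 5 lists for gene list tests of iTSC vs TSC. A group left with 1 library was assumed to vary like the others. For C57BL/6 vs C57BL/6 x 129, leaving out 3F clone 4 or a TSC line left 1 library to carry the strain term. Counts from those fits do not measure strain. With an estimated correlation the gene list tests passed 0 lists for iTSC vs TSC (3 with the preset), 3 for iTSC vs MEF (9) and 2 for iTSC vs ESC (9). Without the 3 clones 7 lists passed for iTSC vs TSC.

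Rescaling to a common total moved the median log2 difference of all genes to -0.22 for iTSC vs TSC, -0.147 for iTSC vs MEF, -0.365 for iTSC vs ESC, -0.127 for TSC vs ESC, 0.184 for iTSC_3F vs iTSC_4F, 0.291 for iTSC_3F vs iTSC_12F, 0.117 for iTSC_4F vs iTSC_12F and 0.144 for C57BL/6 vs C57BL/6 x 129, and quantile normalization moved it to 0.136 for iTSC vs MEF. Rescaling also moved the share of calls that were higher from 41.4% to 23.9% for iTSC vs ESC and from 42.1% to 29.0% for TSC vs ESC, while scaled fragment counts moved the former to 52.1%. Library similarity of TSC and iTSC was 0.835 over the 1000 most variable genes. That of ESC and iTSC was 0.821 by Spearman's rho, 0.803 with a pseudocount of 0.1 and 0.258 over the 1000 genes, that of MEF and iTSC 0.6799 and -0.14 in the last 2 settings, and that of iTSC clones 0.860 over the 1000 genes. In iTSC vs TSC, Cdx2 turned to -0.15 with rescaling, and leaving out a clone or line gave -0.02 to 0.26 for Cdx2 and -0.25 to 0.21 for Elf5. Elf5 was 0.05 on scaled fragment counts. In iTSC vs MEF, Pou5f1 turned to -0.95 on scaled fragment counts, and Igf2 to 0.02 without the 3 clones, with -0.16 to 0.15 when leaving out 1 clone or line. In C57BL/6 vs C57BL/6 x 129, Gm9805 was 0 with duplicate b alone. The causes were not tested. No paired analysis was run because the labels give no pairing between the clones and lines compared. In simulated data for iTSC vs TSC a log2 change of 1.5 was recovered for 46.3% of changed genes, so changes can be missed. The simulated genes varied independently of each other. In the real data some larger differences also missed the threshold, such as Alkbh3 at 2.82 and Krt19 at 2.57 (limma adjusted p = 0.14 and 0.39).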

Other observations

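Some imprinted genes, chosen after their values were seen, differed widely between clones, while others did not, such as Gnas at 342 to 449 FPKM in all 6. The noncoding RNA H19 stood at 7961 FPKM in 4F clone 3, 754 in 4F clone 1 and 59.9 in 3F clone 3, and at 2.98 to 5.61 in the other 3 clones, against 6.14 and 2.504 in the TSC lines and 279 in MEF. Its neighbour Igf2 was lowest in the 2 clones with the highest H19, at 1877 in 4F clone 3 and 1639 in 4F clone 1, against 3340 to 4730 in the other 4 clones. Mest was at 65.9 in 3F clone 4 and 24.8 in 4F clone 3 but at most 1.32 in the other 4 clones, against 77.8 and 31.7 in TSC. The paternally expressed Peg10 reached 867 in 12F clone 4 and 72.8 to 303 in the other clones, with 44.2 and 223 in TSC. Dlk1 was at 86.3 in TSC line 1 and at 0.215 in line 2, with Meg3 at 12.9 and 0.294. None of these was called between factor sets. Mest and Peg10 lie on chromosome 6, where 4F clone 1 stood 0.40 above the median of the iTSC and TSC libraries on the log2 scale.

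The sex chromosome genes were read per library. Xist stood at 1.21 and 5.92 FPKM in the 12F clones 5 and 4, 1.44 and 0.973 in the 4F clones 3 and 1, 0.169 and 0.304 in the 3F clones 4 and 3, 81.7 and 0.681 in TSC lines 1 and 2, 1.08 in ESC and 1.25 in MEF. In the same order Ddx3y stood at 0.0573, 0.00493, 0.0199, 0.162, 0.0656, 0.313, 0.0924, 31.2, 1.72 and 31.3, Eif2s3y at 1.22, 0.33, 0.0983, 0.241, 0.163, 5.86, 0.159, 6.92, 2.44 and 50.3, and Uty at 0.184, 0.166, 0.21, 0.252, 0.209, 0.555, 0.298, 10.9, 0.679 and 8.66. Kdm5d stood at 1.51 in MEF and at most at 0.0451 in every other library.

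The tests of the sex chromosome genes, of the fibroblast transcripts, and of normalization and a gain on chromosome 6 were chosen after the results were seen. For the X-linked median the reference, for the Y-linked genes the minimum level of a marker and the number of markers needed, and for carry-over a second criterion were set after a first output. The tests of depth for Ddx3y and of normalization for the fibroblast transcripts replaced earlier ones whose outcome the scaling or the choice of genes had partly fixed.

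The first pattern was that no clone had Xist, which silences an X chromosome, at the level of TSC line 1, or the Y-linked Ddx3y at the level of TSC line 2 and MEF. The Y-linked Ddx3y stood at 31.2 in TSC line 2 and 31.3 in MEF and at most at 0.313 in the clones, and too few fragments were argued against, since at the TSC line 2 level each clone would have had at least 5977 fragments of it and had at most 85.4. A pair of active X chromosomes was argued against, since the X-linked median relative to TSC and autosomes had upper 95% bounds of at most 0.03 in log2 units, far below 1. For a single X without a Y the markers disagreed, since Eif2s3y reached 84.7% of the TSC line 2 level (6.92 FPKM, against 50.3 in MEF) in 3F clone 3, where Ddx3y was at 1% and Uty at 6.4% of the reference, and 17.7% in 12F clone 5, while 3 Y-linked markers stayed at or below 4.8% in the other 4 clones. It stays open for 3F clone 3 and 12F clone 5, because 1 marker decides nothing and reads shared with the X-linked copy of Eif2s3y were not tested. In the other 4 clones no marker disagreed. RNA levels alone do not show whether a Y chromosome is present, so it was not settled there either.

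The second pattern was fibroblast transcripts in the ESC library. Over the 35 genes of the fixed fibroblast list ESC carried a median of 1.55% of the MEF level, against at most 0.646% in any iTSC or TSC library, and was the highest of these 9 libraries in 21 genes, which argues against the authors' normalization. The first criterion for carry-over took 86 genes at least 100 times higher in MEF than in any iTSC or TSC library. At least 50% of them had to lie within 2 times of the median ratio. It was met at 54.7% in ESC, but also at 61.6% in 4F clone 1 and 51.2% in 3F clone 3. The 86 genes were picked as low in the clones, so low ratios there were fixed in advance. A trace of carry-over in these 2 clones was not tested, so they cannot serve as controls. The criterion therefore cannot decide for ESC, and carry-over was left open. A second criterion, set after the ratios were seen, argues only against RNA with the exact makeup of the MEF library, since 5 of 55 abundant transcripts, among them Mgp (2293 FPKM in MEF, 0.604 in ESC) and Cxcl12 (410 and 0.517), lay under 0.2 of the median ratio. Fibroblasts of another makeup, such as feeder cells, therefore stay open, and low expression by the ESC themselves was not tested. The Y-linked Ddx3y stood at 1.72 FPKM in ESC against 31.3 in MEF, and Eif2s3y at 2.44 against 50.3. Uty stood at 0.679 against 8.66 and Kdm5d at 0.0451 against 1.51. Carry-over from cells that express these genes would give partial levels. Each of these ratios to MEF, however, lay above the 1.55% median of the fibroblast list, though within the range of 0.017% to 8.65% over the 86 genes. The ratios therefore do not decide on carry-over, and weak expression by the ESC was not excluded.

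The third pattern was chromosome 6 in 4F clone 1. Each library was centred on its autosomes. The median of 429 genes was then 0.40 above the per-gene median of the iTSC and TSC libraries on the log2 scale (1.32-fold). It was 0.41 above the other autosomes of the same library, which after the centring is nearly the same quantity. The comparison therefore could not test normalization, though a scale factor common to the library is removed by the centring. All 15 windows of 10 Mb (100%) had a median above 0.2, against 20 of 228 windows (8.8%) elsewhere, which argues against a few co-regulated clusters. A gain of the chromosome in part or all of that culture may account for the median of 0.40, as a hypothesis. The largest autosomal shift of any other library was 0.261.

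The calls between iTSC and TSC were set against other splits of the 8 libraries. Of 28 splits into 6 and 2, 2 gave at least 5 calls, the real one included, and the highest other count was 160, so chance could not be excluded. That split set 12F clone 5 and 4F clone 3 apart from the rest. These 2 clones thus differed from the other 6 libraries in more called genes than iTSC from TSC, and the cause was not tested. Both clones had high mitochondrial shares (10.9% and 9.90%), as did 12F clone 4 (9.48%), whose splits with either of them called 3 and 2 genes.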
